A study of Mus musculus with 12 samples.

How the data were processed

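Small RNA was sequenced from hand-collected mouse oocytes in 12 libraries, 4 for each of 3 groups: wild type, Khdc3-null, and genetically wild type mice with Khdc3-null grandfathers (descendants). Per the labels, total RNA was isolated with the PicoPure kit, which is made for small inputs, and libraries were built with the NEXTFLEX small RNA kit, in which adapters are ligated to both ends of the RNA. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with Bowtie2, whose version was not stated. Treatment of reads that align to several loci was not stated either. This bears on hairpins and tRNA loci of near-identical sequence, and such loci cannot be taken as independent measurements.

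The deposited table gives 2030 features in RPM, the reads of a feature scaled to a common total of mapped reads, with 1 added to every value. The features are 1123 miRNA hairpins, 467 piRNA loci (250 named after a gene and 217 after a chromosome band), 435 tRNA loci and 5 forms of rRNA. After 1 was subtracted, 100% of the values were whole multiples of a fixed step per library within 0.01 reads, with a largest departure of 3.74e-05 reads, and the step gave the mapped reads per library. Mapped reads ranged from 2918620 to 7640554, and the listed features held between 87.8% and 96.3% of them. A count of 0 allows up to 3 reads, which is 1.03 RPM in the shallowest and 0.393 RPM in the deepest library. Reads carry no molecular identifiers, so this limit covers counting error only. Raw reads were not used here.

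Differences between groups were tested with limma 3.58.1 in R 4.3.3, with a trend of the variance on abundance, on log2(RPM + 1) of all 12 libraries in a common fit of 3 group means, since the labels give no batch, litter or pairing. Features were kept when they reached 1.61 RPM, equal to 10 reads at the median depth, in at least 4 libraries. This kept 1889 features (1038 miRNA, 457 piRNA, 389 tRNA and 5 rRNA) and removed 141. The threshold was a Benjamini-Hochberg adjusted p under 0.05 for each comparison, and fold changes refer to RPM + 1. Any difference among the 3 groups was tested with limma's F test. Shares of the small RNA classes, scores of lists (the mean log2 value of the members) and sums over tRNA isotypes were compared with exact two-sided permutation tests over the 70 assignments of 8 libraries to 4 and 4, for which the smallest p is 0.0286. The tests planned for tables of read counts, with edgeR and DESeq2, were not run, because the table was deposited as normalised values, for which limma had been planned. The reads that the step of each library gives were used for limma-voom, as another setting, and for a comparison of libraries at equal depth.

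The lists of miRNAs were fixed before the data were examined: the let-7 family, the miR-17~92 cluster and its paralogs, the miR-290 and miR-302 clusters, the imprinted Dlk1-Dio3 cluster, the Sfmbt2 cluster, an X-linked gonadal cluster, miRNAs of hepatic lipid and glucose metabolism, the miR-200 and miR-183 families, and markers of granulosa cells, of stroma and vessels, of erythrocytes, of leukocytes, and of tissues absent from the ovary. The design, the tests and most of the other settings tried were fixed at the same time. For tRNAs the design named isoacceptors, but the loci were pooled by amino acid over all anticodons, here called isotypes. Each small RNA class and each tRNA isotype with at least 5 tested features was added as a list, which gave 36 lists. They were tested with camera from limma, which compares the members with all other features, with a preset correlation of 0.01 between members and again with the correlation estimated from the residuals. Some lists share members, such as Mir214 between granulosa and stroma and Mir143 between stroma and metabolism. All 15 stroma members were tested, and whether oocytes make these hairpins themselves cannot be read from the libraries, since attached cells would give the same reads. Lists of mRNA markers could not be tested, since the table lists no mRNAs.

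The rule for naming features was likewise fixed. It takes, per comparison, the 10 largest rises and 10 largest falls among features past the threshold whose groups do not overlap. As none passed, the 10 features of smallest p were named instead and are said not to pass. The rule adds the 5 most abundant features, up to 4 members of highest abundance per list and any list member past the threshold. Positions are those of GENCODE M21 on mm10 for 72 of the 73 named miRNA hairpins, and of RefSeq for Mirlet7k.

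The test was checked on simulated data with the depth and spread of these libraries, in which 200 of 1889 features were changed. Of the features changed 1.5-fold, 16.4% to 26.9% were recovered over the 3 comparisons, of those changed 2-fold 40.3% to 52.2%, and of those changed 4-fold 80.3% to 84.8%, with 4 to 6 false calls per comparison. Features were drawn independently of each other, and many changes at once ease the adjusted threshold. With few changes or correlated features, recovery could be lower. Agreement of both comparisons with wild type was set against 100 simulations of unchanged groups with shared controls. In these the residuals of all 12 libraries were assigned to the 3 groups at random. The tools for positions and figures were Python 3.11.15 and matplotlib 3.10.9. Alternatives covered the scaling, the filter, the pseudocount, the weights and spread of the test, the feature set, merged loci, the threshold and the omission of each library in turn.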

Results

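Small RNA libraries were made from oocytes that had been collected by hand from the ovaries of unstimulated mice. The series concerns Khdc3, a maternal-effect gene whose product belongs to the subcortical maternal complex, a protein assembly of the oocyte and early embryo. It asks how this gene bears on metabolism across generations. Of the 12 libraries, 4 came from wild type mice of wild type ancestry and 4 from Khdc3-null mice. The other 4 came from genetically wild type mice whose grandfathers were Khdc3-null and whose grandmothers were wild type. This last group is called descendants here. The labels do not say whether the 4 libraries of a group came from separate animals, so every p-value refers to the spread between libraries. Mapped reads per library numbered 6166378 ± 1441771 (SD, n = 4) in wild type, 5215201 ± 2179632 (SD, n = 4) in Khdc3-null and 6188353 ± 984492 (SD, n = 4) in descendant oocytes, with a range of 2918620 to 7640554. Abundance is given in RPM, the reads of a feature scaled to a common total of mapped reads. Counting error alone allows a feature with 0 reads a level of up to 1.03 RPM in the shallowest library and 0.393 RPM in the deepest. The level of Khdc3 itself was not analysed here, since the features were loci of small RNAs. The genotype labels were therefore not checked against the targeted gene.

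The libraries were dominated by fragments of ribosomal RNA, and no share of a small RNA class passed the adjusted exact test between the 3 groups. In wild type oocytes 56.2% ± 0.624 (SD, n = 4) of the listed reads lay on rRNA, 19.8% ± 0.611 on loci of PIWI-interacting RNAs (piRNAs, which silence transposons in the germ line), 16.4% ± 0.533 on miRNA hairpins and 7.65% ± 0.510 on tRNA loci. In descendants the rRNA share was 57.9% ± 2.34 and the miRNA share 15.5% ± 0.791, and in Khdc3-null oocytes these shares were 56.2% ± 0.491 and 16.3% ± 0.431. None of the 12 comparisons of a share passed an exact two-sided permutation test after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.549 in these exact tests. The smallest exact p that 4 against 4 libraries can give is 0.0286. After adjustment over the 12 comparisons, a single share could therefore not pass even if its groups did not overlap. The adjusted result is thus no evidence of equal shares. Before adjustment the lowest exact permutation p was 0.114, for the miRNA share of descendants against wild type and against Khdc3-null. The piRNA share was 19.4% ± 1.39 in Khdc3-null and 19.4% ± 1.12 in descendant oocytes, and the tRNA share was 8.15% ± 0.614 and 7.24% ± 0.768.

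**Figure D1:**
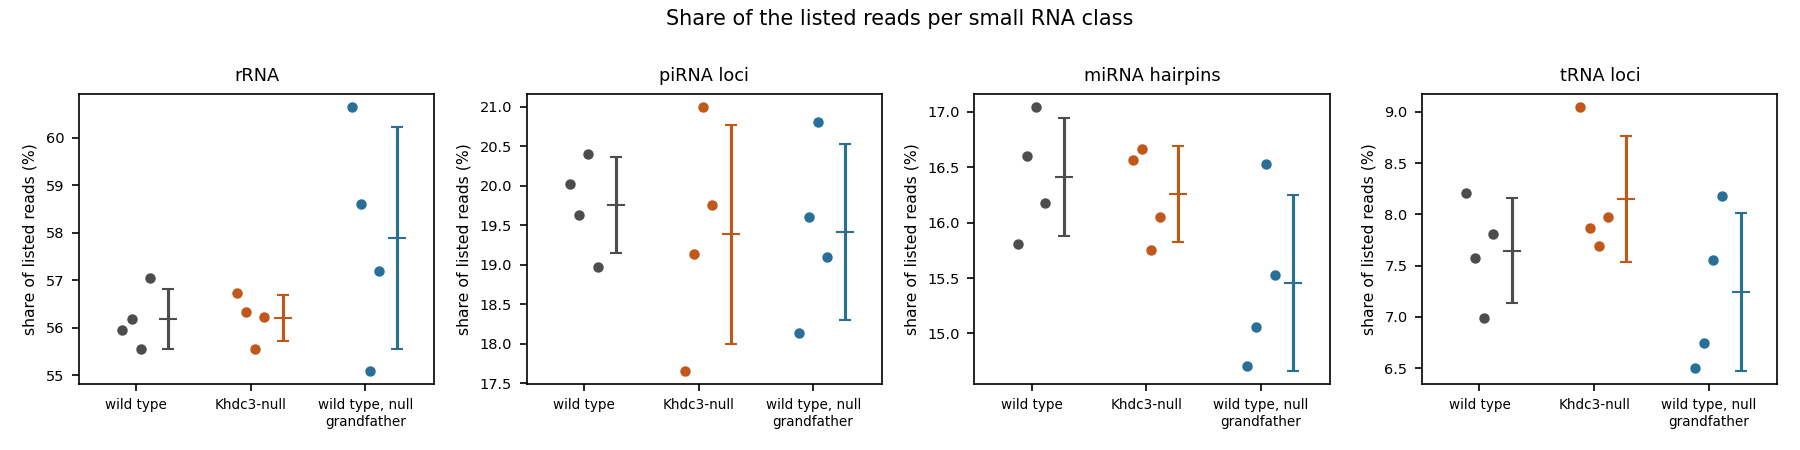
Share of the listed reads (%, vertical axes, which do not start at 0) on rRNA, piRNA loci, miRNA hairpins and tRNA loci in wild type, Khdc3-null and descendant oocytes (points, single libraries; dash and bar, mean and SD, n = 4). The rRNA share of the descendant libraries was the most spread, with a mean of 57.9% and an SD of 2.34, against 56.2% and 0.624 in wild type.

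The comparison of Khdc3-null with wild type oocytes addresses the effect of losing the gene on the small RNAs of the oocyte. No small RNA passed the threshold, and the 10 features of smallest p were all miRNA hairpins, which ranged from scarce to abundant. Mir6384, in an intron of the glypican gene Gpc3 (chromosome X, 52378121 to 52378181), stood at 9.59 ± 3.35 RPM (SD, n = 4) in Khdc3-null and 1.35 ± 0.349 RPM in wild type oocytes, a 4.35-fold higher level on the scale with 1 RPM added (log2 SE 0.39, adjusted p = 0.147). Mirlet7k, an intergenic member of the let-7 family (chromosome 5, 147283189 to 147283298), stood at 73.4 ± 10.0 RPM against 119 ± 12.6 RPM (log2 -0.69, SE 0.16, adjusted p = 0.389). Mir6947, in an intron of Actr8, which codes for a subunit of a chromatin remodelling complex (chromosome 14, 29988888 to 29988952), stood at 0.463 ± 0.284 RPM against 7.01 ± 1.75 RPM, 5.45-fold lower on the same scale (log2 SE 0.56, adjusted p = 0.389). The size of such folds at low abundance depends on the constant added and the tool, with log2 values of 0.77 to 2.89 for Mir6384 and -4.01 to -0.70 for Mir6947 over the settings run. Mir107, which lies in an intron of the pantothenate kinase gene Pank1 (chromosome 19, 34820687 to 34820773), stood at 68.0 ± 27.8 RPM against 27.2 ± 6.88 RPM (log2 1.23, SE 0.32, adjusted p = 0.585).

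The other hairpins among the 10 of smallest p are given as Khdc3-null against wild type. Mir7224 in an intron of B3galt1 stood at 8.48 ± 4.03 against 1.27 ± 1.69 RPM, but the groups overlapped, and without wild type replicate 4, at 3.75 RPM, the wild type mean was 0.438 RPM. Higher means were also found for Mir6539 in an intron of Dock5, at 29.3 against 13.0 RPM, and for Mir6930 in an intron of Slc25a39, at 29.8 against 14.7 RPM, where the groups overlapped. Lower means were found for the intergenic Mir296, at 14.5 against 30.0 RPM, and for Mir6978 in an intron of the complement gene C3 (chromosome 17, 57217172 to 57217228), at 911 ± 76.8 against 1161 ± 104 RPM. Mir8113, in a coding exon of Cd27, stood at 306 ± 36.1 against 417 ± 34.9 RPM.

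Among the miRNA families and cell type lists fixed in advance, the let-7 family, which represses genes of growth and developmental timing, stood lower as a group in Khdc3-null oocytes. Of its 14 measured members, 12 were lower and 2 higher than in wild type, with a median log2 change of -0.23. None passed over all features and 1, Mirlet7k, passed when adjusted over the list alone. The list passed with the preset correlation between members (adjusted p = 0.00852) but not with the correlation estimated from these libraries (adjusted p = 0.917 with an estimated correlation). Its most abundant members, Mirlet7c-1 and Mirlet7c-2, stood at 3147 ± 830 and 2885 ± 811 RPM in Khdc3-null against 3706 ± 538 and 3484 ± 509 RPM in wild type oocytes. Such copies are not independent measurements, and the estimated correlation between members of the list was 0.41. The call was lost without wild type replicate 3 or 4 or Khdc3-null replicate 2, 3 or 4, with adjusted p between 0.0632 and 0.250 and medians between -0.23 and -0.16. It was also lost with median-of-ratios scaling (median -0.17, adjusted p = 0.0633). The list of miRNAs with roles in hepatic lipid and glucose metabolism had a median log2 change of 0.04, with 19 members higher and 14 lower (adjusted p = 0.196). Markers of stroma and vessels were not called either, with a median of 0.04 and 9 of 15 higher (adjusted p = 0.436). Granulosa markers had a median of -0.01, with 8 of 14 lower (adjusted p = 0.818), and the test pointed up while the median and mean were below 0. Leukocyte markers had a median of 0.19 but a mean of -0.08 (adjusted p = 0.465). Erythrocyte markers had a median of 0.45, with 3 of 4 higher (adjusted p = 0.224). The erythrocyte miRNA Mir451a stood at 28.2 ± 29.9 RPM in Khdc3-null and 9.94 ± 8.14 RPM in wild type oocytes.

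In limma, 0 of the 1889 small RNAs tested differed between Khdc3-null and wild type oocytes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 95, of which 29 were higher and 66 lower, where 94.5 are expected by chance. Limma-voom with sample quality weights also gave 0, with 172 at the unadjusted threshold, and limma-voom without them gave 0 and 90. The 2 groups did not overlap in 60 features, or 3.18%, where chance gives 2.86%. The 95% confidence intervals reached a median of 0.67 log2 units to either side of the estimate. They excluded a 2-fold change of RPM + 1 in 1062 features (56.2%). For scarce features this does not exclude a 2-fold change of RPM. Khdc3-null replicate 1 stood apart from the other libraries, with a median correlation of 0.918 with them. Without it 1 feature, Mir6384, passed (log2 2.37, adjusted p = 0.0473) and 125 did at the unadjusted threshold. Without wild type replicate 2 the unadjusted number was 63.

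The comparison of descendants with wild type oocytes asks whether a Khdc3-null grandfather leaves a difference in mice that carry no mutation. No small RNA passed the threshold. As a group, miRNAs typical of smooth muscle, stroma and vessels were lower in descendants. In this list 14 of 15 members were lower, with a median log2 change of -0.32 (adjusted p = 1.7e-06 with the preset correlation, adjusted p = 0.231 with an estimated correlation). The mean level of the list per library was 8.73 ± 0.128 (log2 RPM + 1; SD, n = 4) in descendants and 9.01 ± 0.0450 in wild type oocytes, and every descendant library lay below every wild type and Khdc3-null library. The exact permutation p of this contrast was 0.0286, the smallest that can be had, and 0.411 after adjustment over the 36 lists. A single list could not pass this adjusted exact test, whatever its difference.

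Of the abundant members of the stroma list, Mir10b, in an intron shared by Hoxd3 and Hoxd4 (chromosome 2, 74726070 to 74726137), stood at 2849 ± 387 RPM in descendants and 4220 ± 1171 RPM in wild type oocytes (log2 -0.54, SE 0.17, adjusted p = 0.946), and the groups overlapped. Mir143, a smooth muscle miRNA that is also on the metabolic list, stood at 2779 ± 647 against 3031 ± 303 RPM (log2 -0.15, SE 0.15). Mir99a, within its host transcript Mir99ahg, stood at 1864 ± 117 against 2186 ± 435 RPM (log2 -0.21, SE 0.16). No member passed over all features or when adjusted over the list alone, and 5 were lower at the unadjusted threshold. Beside this, the erythrocyte markers had a median of 0.23 (adjusted p = 0.30), with Mir451a at 21.7 ± 15.0 RPM in descendants. The leukocyte markers had a median of -0.21 (adjusted p = 0.718). Granulosa cell markers were lower in 12 of 14 members, with a median of -0.28 (adjusted p = 0.00789, and adjusted p = 0.605 with an estimated correlation). The most abundant granulosa member, the intergenic Mir322, stood at 2366 ± 321 against 2603 ± 433 RPM. It lies close to Mir351 of the same list on chromosome X, so the granulosa members may not be independent. The granulosa call was lost without wild type replicate 3 or descendant replicate 3 or 4, with adjusted p between 0.0540 and 0.0773 and medians between -0.18 and -0.16.

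The let-7 family was lower in descendants in 10 of 14 members, 8 of them at the unadjusted threshold, with a median of -0.37 (adjusted p = 5.03e-05, and adjusted p = 0.817 with an estimated correlation). Copies such as Mirlet7c-1 and Mirlet7c-2 count as separate members here but are not independent. Mirlet7c-1, in the same host transcript as Mir99a, stood at 2804 ± 374 RPM in descendants and 3706 ± 538 RPM in wild type oocytes, and Mirlet7b, in Lncppara, at 1887 ± 340 against 2562 ± 334 RPM. No let-7 member passed when adjusted over the list alone. The metabolic list was not called (median -0.15, 24 of 33 lower, adjusted p = 0.281), but 3 of its members passed when adjusted over the list alone and 0 over all features. Mir26a-1, in an intron of Ctdspl (chromosome 9, 119031796 to 119031885), stood at 1019 ± 137 against 1377 ± 130 RPM (log2 -0.44, SE 0.13). Mir26a-2, within Ctdsp2 (chromosome 10, 126995530 to 126995613), stood at 909 ± 133 against 1302 ± 148 RPM (log2 -0.52, SE 0.13, adjusted p = 0.946 over all features). The last of these members was Mir107, at 60.7 ± 20.2 against 27.2 ± 6.88 RPM (log2 1.11, SE 0.32). The Mir26a loci give the same main mature miRNA, so their values are not independent.

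The feature of smallest p was the intergenic Mir195a (chromosome 11, 70235042 to 70235135), of a family that represses cell cycle genes. It stood at 260 ± 64.3 RPM in descendants and 447 ± 88.6 RPM in wild type oocytes (log2 -0.79, SE 0.17, adjusted p = 0.813). The rest of the 10 of smallest p, beside those named above, included Mir1247 in an exon of Dio3os, at 52.8 against 91.3 RPM, and Mir7224, at 7.35 ± 3.49 against 1.27 ± 1.69 RPM. For Mir7224 these groups overlapped too, and the wild type mean rested on replicate 4 as above. They also included Mir301 in an intron of Ska2, at 10.6 ± 5.46 against 2.88 ± 2.11 RPM, and Mir1983, at 338 against 239 RPM. A leucine tRNA locus, chr13.trna65-LeuCAA, stood at 8.71 against 18.8 RPM. In limma 0 of 1889 features passed and 77 did at the unadjusted threshold, 34 higher and 43 lower, with 94.5 expected by chance. Limma-voom gave 0 with quality weights and 0 without, and 101 and 94 at the unadjusted threshold. The groups did not overlap in 52 features (2.75%, where chance gives 2.86%). The confidence intervals excluded a 2-fold change of RPM + 1 in 1041 features (55.1%).

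**Figure D2:**
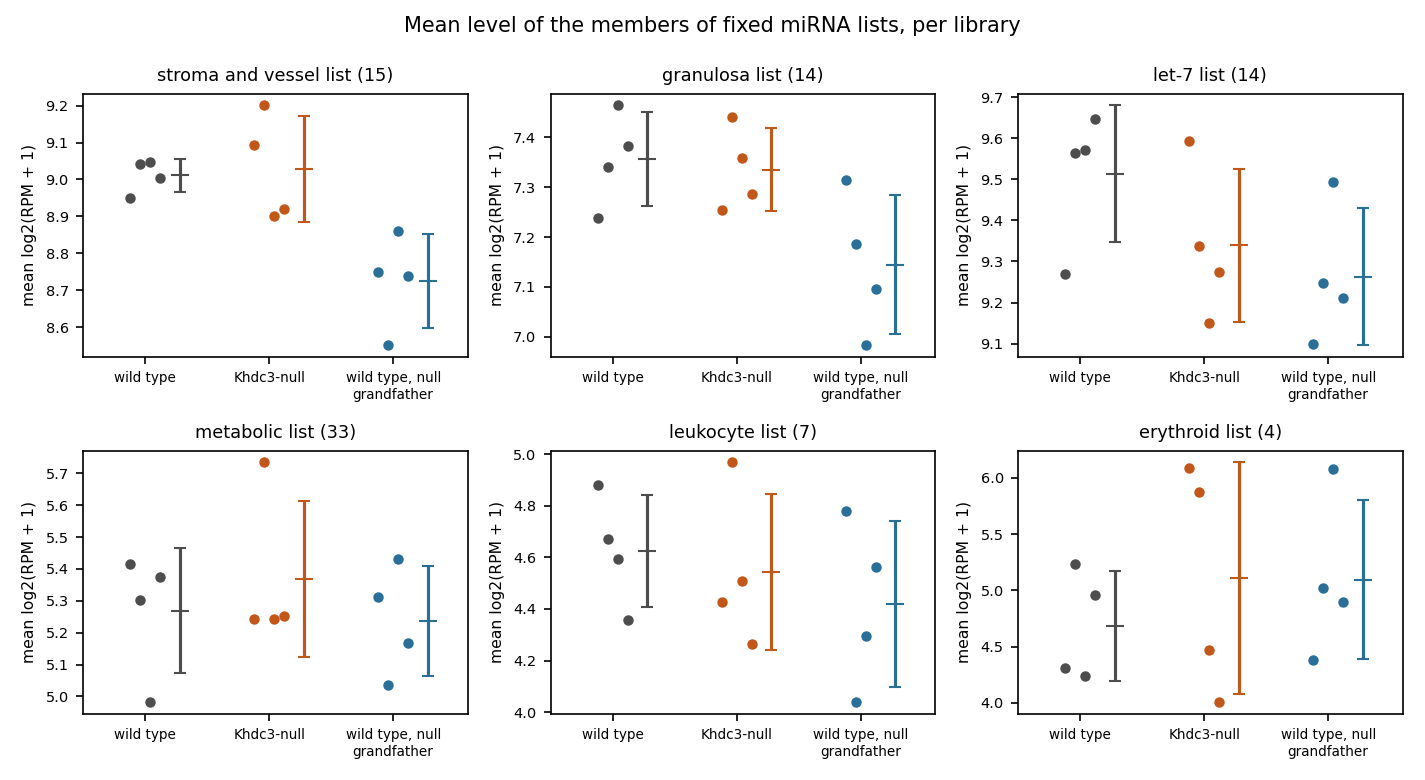
Mean log2(RPM + 1) of the members of 6 miRNA lists (vertical axes, which do not start at 0; number of members in parentheses) in wild type, Khdc3-null and descendant oocytes (points, single libraries; dash and bar, mean and SD, n = 4). The descendant libraries lay between 8.55 and 8.86 on the stroma and vessel list, below the range of 8.95 to 9.05 in wild type and of 8.90 to 9.20 in Khdc3-null, while the ranges of the groups overlapped on the other lists.

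The direct contrast of descendants with Khdc3-null oocytes asks where the grandchildren of null males differ from the mutants themselves. The stroma list was lower in descendants here too, in 14 of 15 members with a median log2 change of -0.31 (adjusted p = 2.97e-08, and adjusted p = 0.117 with an estimated correlation). The metabolic list was lower in 21 of 33 members, with a median of -0.20 (adjusted p = 0.0138, and adjusted p = 0.682 with an estimated correlation). Granulosa markers were lower in 10 of 14 members, with a median of -0.22 (adjusted p = 0.0138, and adjusted p = 0.682 with an estimated correlation). The erythrocyte markers had a median of -0.09 (adjusted p = 0.846) and the leukocyte markers one of -0.19 (adjusted p = 0.346). Mir26a-1 stood at 1019 ± 137 RPM in descendants and 1440 ± 206 RPM in Khdc3-null oocytes (log2 -0.50, SE 0.13, adjusted p = 0.656), and Mir26a-2 at 909 ± 133 against 1350 ± 197 RPM (log2 -0.57, SE 0.13, adjusted p = 0.451). These were the 2 members of the metabolic list that passed when adjusted over the list alone.

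In the other direction, Mirlet7k stood at 122 ± 14.2 RPM in descendants, near its wild type level of 119 ± 12.6 RPM, and at 73.4 ± 10.0 RPM in Khdc3-null oocytes (log2 0.73, SE 0.16, adjusted p = 0.451). It was the 1 let-7 member that passed when adjusted over the list alone. The list as a whole had a median of -0.14 with 12 of 14 lower (adjusted p = 0.380). Mir6978 followed the same order, at 1259 ± 125 RPM in descendants and 911 ± 76.8 RPM in Khdc3-null oocytes (log2 0.46, SE 0.11, adjusted p = 0.451), with 1161 ± 104 RPM in wild type. Mir345, in Slc25a47 (chromosome 12, 108836973 to 108837068), stood at 274 ± 57.7 RPM in descendants and 391 ± 26.1 RPM in Khdc3-null oocytes. The remaining features of smallest p were scarce, all with adjusted p = 0.658. Mir7674 stood at 12.7 ± 11.6 against 0.768 ± 1.10 RPM, and the groups overlapped, with 1.61 RPM in the lowest descendant and 2.40 RPM in the highest Khdc3-null library. Its means were 8.13 RPM without descendant replicate 4 and 0.225 RPM without Khdc3-null replicate 2. Mir1941 stood at 15.7 against 35.3 RPM, where the groups overlapped, and Mir3087 at 20.0 ± 6.31 against 5.73 ± 6.21 RPM. Mir344e stood at 7.76 ± 2.17 against 1.77 ± 1.81 RPM and a threonine tRNA locus, chr13.trna104-ThrAGT, at 4.09 ± 2.22 against 0.475 ± 0.434 RPM. The Khdc3-null means of these last features also moved with single libraries, from 3.90 to 7.65 RPM for Mir3087, 1.17 to 2.36 RPM for Mir344e and 0.283 to 0.634 RPM for chr13.trna104-ThrAGT.

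In limma 0 of 1889 features passed between descendants and Khdc3-null oocytes, and 121 did at the unadjusted threshold, 69 higher and 52 lower, with 94.5 expected by chance. Limma-voom gave 0 with quality weights and 0 without, and 147 and 128 at the unadjusted threshold. The groups did not overlap in 57 features (3.02%, where chance gives 2.86%). The confidence intervals excluded a 2-fold change of RPM + 1 in 1025 features (54.3%). The metabolic call was lost without Khdc3-null replicate 1 or 2 or descendant replicate 2 (adjusted p between 0.0502 and 0.296, medians between -0.20 and -0.12). The granulosa call was lost without Khdc3-null replicate 2 or descendant replicate 3 or 4 (adjusted p between 0.0545 and 0.109, medians between -0.21 and -0.15). A limma F test of any difference among the 3 groups also gave 0 features, with 93 at the unadjusted threshold and a lowest adjusted p of 0.472. Limma-voom gave 0 with quality weights and 0 without, and 162 and 97 at the unadjusted threshold.

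**Figure D3:**
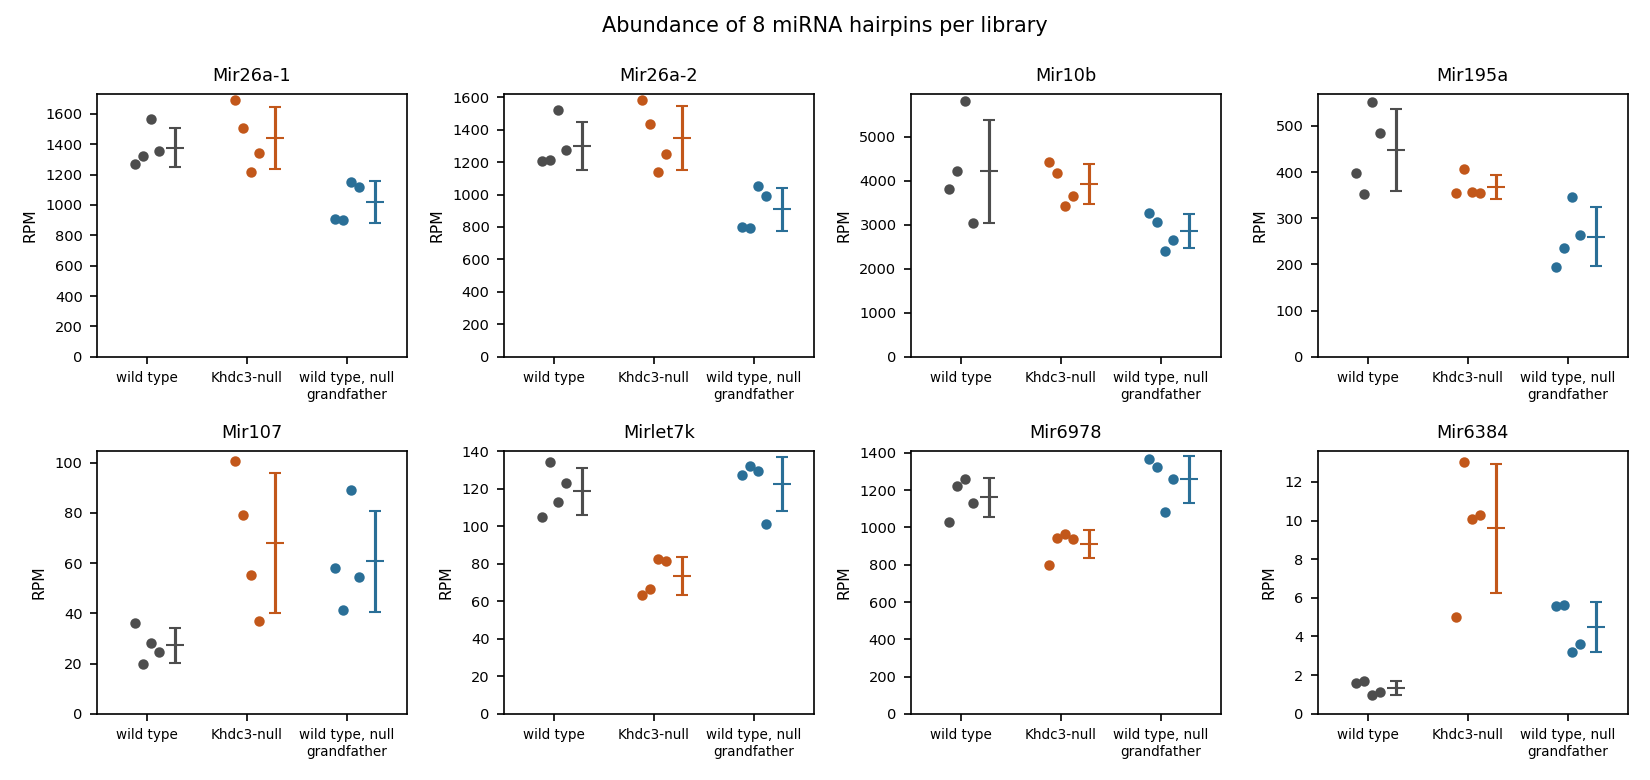
Abundance (RPM, vertical axes from 0) of 8 miRNA hairpins in wild type, Khdc3-null and descendant oocytes (points, single libraries; dash and bar, mean and SD, n = 4). Mir26a-1, Mir26a-2 and Mir195a were lowest in descendants, with means of 1019, 909 and 260 RPM. Mirlet7k and Mir6978 were lowest in Khdc3-null oocytes, with means of 73.4 and 911 RPM; none of the 8 passed the test over all features.

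Whether descendants resembled Khdc3-null oocytes was asked by setting both comparisons with wild type side by side. Mir107 and Mir7224 were among the 10 features of smallest p in both, and higher than in wild type in both, whereas Mirlet7k and Mir6978 were lower only in the means of Khdc3-null oocytes. Across the 1889 features, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.421 and a covariance of 0.0749. Both comparisons use the same wild type libraries. Unchanged groups simulated against shared controls gave a median correlation of 0.499, with 95% of values between 0.0694 and 0.761, and a median covariance of 0.102. With the 4 wild type libraries divided so that each comparison had its own 2 controls, the mean correlation over the 6 divisions was 0.0332, with a range of -0.0474 to 0.0688. At the unadjusted threshold 7 features were higher in both comparisons. The simulation gave a median of 9.5 for unchanged groups with shared controls, and 0.522 are expected for independent lists. Lower in both were 8 features, where the simulation gave 7 and independent lists give 1.5. The middle 95% of the simulated numbers reached from 0 to 28.5 for higher and from 0 to 27.3 for lower features. The correlation, the covariance and both numbers thus lay within the simulated range. The simulation assigned the residuals of all 12 libraries to the groups at random. Khdc3-null replicate 1, which stood apart, could therefore fall among the shared controls. The width of the range may reflect the place of that library as well as the sharing of controls.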

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

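The tests of read depth and of RNA from another cell type were chosen only after the result was seen. In 150 groups of 4 libraries, each for a measure of the libraries or a named feature or list, 8 groups (5.33%) held a library far from the others by Dixon's test. Chance gives about 1 in 20 groups, or 5%.

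Khdc3-null replicate 1 held 3 of these 8 values, namely 62 tested features at 0 reads, where the other Khdc3-null libraries had 3 to 11, a median correlation of 0.918 with all other libraries, where they had 0.952 to 0.957, and 320066 RPM of 45S rRNA, where they had 340610 to 341413 RPM. Fewer reads alone could not give this, because at the depth of the shallowest library 70.8 features would be at 0 in this library and at most 22.6 in any other. For a loss of rare molecules at low input, the prediction was that the deviation of scarce features would widen most. Over 4 bins of abundance the deviation was 1.54 to 1.81 times that of the other libraries. Its ratio between the scarcest and the most abundant bin was 0.942, against a highest other value of 1.38, so the prediction was not met. This cannot exclude such a loss, since the constant of 1 RPM dampens the deviation of scarce features and the number of features at 0 was itself high. RNA from another cell type cannot be told apart from other faults of a library, since the erythrocyte list stood higher than in all 11 other libraries, at 6.09 (mean log2 RPM + 1), but by less than their SD of 0.670, with 6.08 in the next library. The list of muscle, liver and brain markers was the lowest, at 2.87 against 3.29 to 4.20 in the other libraries. The granulosa, stroma and leukocyte lists lay within the range of the others. No biological explanation was tested.

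The remaining values are given without explanation. Khdc3-null replicate 2 had a score of 5.73 (mean log2 RPM + 1) on the metabolic list, where the other libraries of its group had 5.24 to 5.25. The same library had 406 RPM of Mir195a, where the others had 354 to 357 RPM. Wild type replicate 2 had 0.770 RPM of Mir7674, where the others had 3.04 to 3.46 RPM. Descendant replicate 4 had 101 RPM of Mirlet7k, where the others had 127 to 132 RPM. Descendant replicate 3 had 7.39 RPM of chr13.trna104-ThrAGT, where the others had 2.69 to 3.41 RPM.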

How the results depend on the processing

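The settings chosen only after the data were seen were scaling to the listed reads or to reads outside rRNA, limma-voom without weights, robust empirical Bayes, merging of near-identical loci, shares of all mapped reads and the focus on Khdc3-null replicate 1; the rest were fixed before the data were examined. The number of small RNAs past the adjusted threshold was 0 in each setting run, except that without Khdc3-null replicate 1 the comparison of Khdc3-null with wild type gave 1 (range 0 to 1 over single omitted libraries). The unadjusted numbers ranged from 47 to 172, 46 to 111 and 68 to 159 in the 3 comparisons and from 50 to 162 for any difference, lowest where fewer features were tested; the cause of the highest was not tested. No named feature reversed over 794 values, but the sizes of scarce features moved widely. Their log2 changes were lowest in size with a pseudocount of 10 and ranged from -4.01 to -0.70 for Mir6947, 0.77 to 2.89 for Mir6384 and 0.70 to 3.34 for Mir7224 in Khdc3-null against wild type, and from 0.61 to 3.12 for Mir7224 and 0.66 to 2.12 for Mir301 in descendants against wild type. In descendants against Khdc3-null they ranged from 0.93 to 4.33 for Mir7674, 1.00 to 3.43 for Mir3087, 0.60 to 3.10 for Mir344e and 0.42 to 3.32 for chr13.trna104-ThrAGT. Scaling moved the median change of all features by at most 0.06 (log2). Of the 21 list calls, 4 were kept in all settings but the estimated correlation, which left 0 calls in Khdc3-null against wild type, 0 in descendants against wild type and 0 in descendants against Khdc3-null. The estimate was above the preset value for 35 of the 36 lists, which widens their null by construction; the miR-200 and miR-183 list, not called, was the exception. Other scalings, filters or pseudocounts ended 6 calls: let-7 and methionine in Khdc3-null against wild type, cysteine in descendants against wild type, and glutamine, glutamate and isoleucine in descendants against Khdc3-null. Over single omitted libraries the number of lists called ranged from 1 to 9, 4 to 10 and 4 to 7. In descendants against Khdc3-null the median of the glutamate tRNA list ranged from -0.45 to 0.055, reversing without Khdc3-null replicate 1. The correlation of both comparisons with wild type went from 0.421 to 0.0332 with divided controls, which by construction removes the shared wild type libraries. Differences in class shares depended on single libraries, and some changed sign. In Khdc3-null against wild type they ranged over single omitted libraries from -0.351 to 0.0613 percentage points for miRNA, -0.907 to 0.207 for piRNA and -0.187 to 0.305 for rRNA, which was -0.407 as a share of mapped reads. The piRNA difference ranged from -0.810 to 0.0840 in descendants against wild type, with 0.246 without the most abundant feature and 0.190 as a share of mapped reads, and from -0.550 to 0.564 in descendants against Khdc3-null. Without a change of sign, the rRNA difference ranged from 0.777 to 2.63 in descendants against wild type and 0.756 to 2.61 against Khdc3-null. The tRNA difference ranged from 0.196 to 0.686 in Khdc3-null against wild type, and in descendants from -0.714 to -0.155 against wild type and -1.21 to -0.600 against Khdc3-null. The miRNA difference ranged in descendants from -1.31 to -0.706 against wild type and -1.16 to -0.555 against Khdc3-null. Without descendant replicate 3, every descendant library had a higher rRNA share and a lower miRNA share than every wild type and Khdc3-null library. Over all settings of the class shares the lowest exact permutation p before adjustment was 0.0286. The cause of these changes was not tested. The edgeR, DESeq2 and robust quasi-likelihood tests were not run, since they were planned for a table deposited as read counts. Depth limits the scarce features most, since 0 reads allow up to 1.03 RPM.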

Other observations

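The tests of RNA from other cells, of stroma cells alone, of scaling by rRNA and of tRNA isotype sums were chosen only after the result was seen. None of the 5 small RNAs with the highest mean over all libraries passed in limma between the groups. The 45S, 28S and 18S forms of rRNA and an alanine tRNA locus, chr13.trna71-AlaAGC, led the libraries, the last at 20711 ± 3290 RPM (SD, n = 4) in wild type, 26292 ± 2021 RPM in Khdc3-null and 20480 ± 7528 RPM in descendant oocytes. The most abundant piRNA locus, pi-D10Wsu102e.2, stood at 8105, 6457 and 8139 RPM in the same order. As lists, none of the 4 small RNA classes was called in any comparison, and the lowest adjusted p was 0.0800, for rRNA in descendants against wild type.

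Of the miRNA clusters, none of the following was called. The imprinted Dlk1-Dio3 cluster had median log2 changes of -0.10 in Khdc3-null against wild type, -0.08 in descendants against wild type and 0.10 in descendants against Khdc3-null. In the same order the miR-290 and miR-302 clusters of the early embryo had -0.17, -0.09 and 0.25, the miR-17~92 cluster and its paralogs 0.08, 0.12 and 0.07, and the X-linked gonadal cluster -0.15, -0.24 and 0.14. The Sfmbt2 list, with 16 of 55 members tested, had -0.18, -0.36 and -0.11, although in the first comparison its mean was 0.04 and its test pointed up. Its members were matched by name, and not all lie in the cluster, since Mir466i lies on chromosome 13 within Cdk13. The miR-200 and miR-183 families had 0.07, 0.07 and -0.02. Markers of muscle, liver and brain had -0.14, -0.10 and 0.28, and in the second comparison the test pointed up. The miRNAs Mir103-1_seq and Mir103-2_seq, chosen after their values were seen because their mature form is nearly that of Mir107, stood at 199 and 160 RPM in wild type, 192 and 150 RPM in Khdc3-null and 183 and 130 RPM in descendant oocytes.

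The miRNAs of smooth muscle, stroma and vessels were lower as a list in descendants than in both other groups with the preset correlation, but not with an estimated correlation (adjusted p = 0.231 with an estimated correlation against wild type and adjusted p = 0.117 with an estimated correlation against Khdc3-null). Scaling by the larger rRNA share is argued against, since the list score scaled among miRNAs alone still differed from wild type by -0.24 (log2, exact permutation p = 0.0286). Reads shared within a family do not alone account for the call with the preset correlation. There 8 of 8 families were lower, and the list of family sums kept an adjusted p of 5.18e-05 with the preset correlation. The family sums were not tested with an estimated correlation. The families are not independent either, as Mir143 and Mir145a lie close together on chromosome 18. Chance stays open, since the list call was lost with an estimated correlation. A smaller share of RNA from all other cells of the ovary and blood stays open. The granulosa and leukocyte scores also differed from wild type by -0.21 and -0.21, near the change of the stroma score (exact permutation p of the differences 0.543 and 0.714). The erythrocyte score of 4 members was instead higher than in wild type by 0.41. Its change lay 0.69 above that of the stroma score without passing (exact permutation p = 0.171). Less RNA from stroma cells alone could give the score difference of -0.29, and so could a difference within the oocytes. No list separates the hairpins of attached cells from those of oocytes. If stroma RNA were lost, its markers should fall by about the same factor. The family sums ranged from -0.15 for miR-143 to -0.50 for miR-10, and this spread was not tested. The fall was not confined to cell markers, since the let-7 list had a median of -0.37, while the miR-17~92 list had 0.12. A difference that follows the Khdc3-null grandfathers stays open and untested.

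Of the 19 tRNA isotypes tested as lists, 8 were called in at least 1 comparison, with 14 calls in all, and each call was lost with an estimated correlation. In Khdc3-null against wild type oocytes the aspartate (median log2 -0.38, 16 of 16 loci lower, adjusted p = 0.00144), histidine (-0.69, 11 of 11, adjusted p = 0.00189), glycine (-0.30, 23 of 29, adjusted p = 0.00852) and glutamine loci (-0.48, 15 of 16, adjusted p = 0.00958) were lower as groups. The methionine loci were higher (0.12, 15 of 19, adjusted p = 0.00144), and all 5 lists had adjusted p = 0.917 with an estimated correlation. In descendants against wild type the aspartate (-0.36, 15 of 16, adjusted p = 0.00384), histidine (-0.57, 9 of 11, adjusted p = 0.0103), isoleucine (-0.39, 13 of 15, adjusted p = 0.0155) and cysteine loci (-0.40, 15 of 20, adjusted p = 0.0383) were lower, each with adjusted p = 0.895 with an estimated correlation. Methionine loci were again higher (0.26, 15 of 19, adjusted p = 0.000237, and adjusted p = 0.817 with an estimated correlation). In descendants against Khdc3-null the cysteine (-0.35, 16 of 20, adjusted p = 0.0130, and adjusted p = 0.682 with an estimated correlation), glutamate (-0.26, 18 of 21, adjusted p = 0.0428, and adjusted p = 0.981 with an estimated correlation) and isoleucine loci (-0.34, 12 of 15, adjusted p = 0.0428) were lower. Glutamine loci were higher there (0.39, 13 of 16, adjusted p = 0.0428), and both this and the isoleucine list had adjusted p = 0.971 with an estimated correlation. No isotype outside these 8 was called, and the lowest adjusted p among them was 0.108.

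Most of these calls were lost when single libraries were left out, some with a smaller median and some with a median near that of all libraries. In Khdc3-null against wild type the aspartate call was lost without wild type replicate 2 or 4 or Khdc3-null replicate 3 or 4 (adjusted p 0.0544 to 0.249, median -0.28 to -0.24). The glutamine call was lost without wild type replicate 4 or Khdc3-null replicate 3 or 4 (0.0797 to 0.249, median -0.46 to -0.43). The glycine call was lost without wild type replicate 1 or 4 or Khdc3-null replicate 2, 3 or 4 (0.0829 to 0.611, median -0.28 to -0.11), and the histidine call without wild type replicate 4 or Khdc3-null replicate 3 (0.122 to 0.156, median -0.49 to -0.47). The methionine call was lost without Khdc3-null replicate 2 (0.138, median 0.067) or with a filter at the median (0.304, median 0.089).

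In descendants against wild type the aspartate call was lost without wild type replicate 2 or 4 or descendant replicate 4 (adjusted p 0.0671 to 0.230, median -0.28 to -0.21), and the histidine call without these or descendant replicate 3 (0.0659 to 0.230, median -0.51 to -0.37). The isoleucine call was lost without wild type replicate 1 or descendant replicate 1 or 2 (0.0513 to 0.147, median -0.38 to -0.18). The cysteine call was lost without wild type replicate 2, 3 or 4, Khdc3-null replicate 1 or descendant replicate 1, 3 or 4 (0.0632 to 0.165, median -0.47 to -0.33). It was also lost with scaling to the listed reads, a filter of at least 10 reads in 4 libraries or a pseudocount of 10 (0.0512 to 0.0907, median -0.45 to -0.11).

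In descendants against Khdc3-null the cysteine call was lost without Khdc3-null replicate 4 (adjusted p 0.0684, median -0.26). The glutamine call was lost without Khdc3-null replicate 3 or 4 or descendant replicate 1, 2 or 4 (0.0526 to 0.285, median 0.27 to 0.48) or with a pseudocount of 10 (0.0567, median 0.18). The glutamate call was lost without Khdc3-null replicate 1 or descendant replicate 3 or 4 (0.377 to 0.716, median -0.27 to 0.055). The isoleucine call was lost without any of the Khdc3-null libraries or descendant replicate 1 or 2 (0.0527 to 0.360, median -0.35 to -0.067). Both were also lost with median-of-ratios or upper quartile scaling, scaling to the listed reads, no filter or a pseudocount of 0.1, and the glutamate call with scaling to reads outside rRNA (adjusted p 0.0535 to 0.0951 for glutamate and 0.0530 to 0.0700 for isoleucine). The medians there were -0.31 to -0.26 for glutamate and -0.39 to -0.30 for isoleucine, about as large as the main values of -0.26 and -0.34.

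Many tRNA loci are close copies, so reads shared between them may let a few molecules move many loci of a list. An isotype here pools loci of different anticodons, however, and not all of its loci need be copies of each other. Among the called isotypes the estimated correlation between loci ran from 0.13 for cysteine to 0.83 for aspartate. When the loci were summed to 1 value per isotype, none passed in limma, with a lowest adjusted p of 0.444, but no single feature passed in these libraries either. The sums were at least as large as the median of the loci in 5 of the 14 calls, such as histidine in Khdc3-null against wild type (log2 -0.78 against -0.69), and 3 were much smaller or opposite, such as cysteine in descendants against wild type (-0.10 against -0.40). Shared reads therefore cannot be told apart from a change of the whole isotype with these sums. A difference in tRNA fragments between the groups stays open and untested.

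At the adjusted threshold the real number was 0, which all 35 splits of the 8 libraries of a comparison reach by definition, so that these splits say nothing about chance. The highest other number was 12 in Khdc3-null against wild type and 0 in both other comparisons. The split with 12 exchanged wild type replicate 3 and Khdc3-null replicate 1 and left the other 6 libraries with their genotype. It was picked as the highest of the other splits, whose median was 0, and whether it exceeds chance was not tested. For the numbers at the unadjusted threshold and of lists called, other splits gave results as large often enough that chance cannot be excluded. At the unadjusted threshold 10 of 35 splits gave at least the real 95 features in Khdc3-null against wild type (highest other 168), 16 of 35 at least 77 in descendants against wild type (highest other 152) and 12 of 35 at least 121 in descendants against Khdc3-null (highest other 227). As many lists were called in 17 of 35 splits for the real 6 (highest other 14), in 7 of 35 for the real 8 (highest other 13) and in 17 of 35 for the real 7 (highest other 13). For any difference among the 3 groups, all 100 splits drawn reach the real 0 by definition, and the highest other was 0.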
